A study of Drosophila melanogaster with 11 samples.

How the data were processed

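The series measured RNA hydroxymethylcytosine and transcript levels in cultured Drosophila S2 cells. Of its 11 samples, 6 were used: 4 polyA RNA-seq libraries (2 control and 2 dTet knockdown libraries) and 2 hMeRIP-seq samples. hMeRIP-seq sequences RNA pulled down with an antibody to hydroxymethylcytosine. It was applied to total RNA of S2 cells edited by CRISPR at yellow, a pigmentation gene that serves as the editing control, or at dTet, the fly gene for the Tet dioxygenase. The other 5 samples, which are both hMeRIP samples of unedited S2 cells and the 3 input libraries, were not analysed here. Groups and replicate numbers follow the labels. The labels do not say whether replicates were separate cultures, so the p-values may measure technical spread only.

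The authors aligned reads with BWA to the dm3 build and called peaks with MACS 1.4. The sources used here do not state the peak threshold, the use of the input, the annotation, the read counter, or whether duplicates were removed. Each deposited RNA-seq file lists 78680 exons of 16509 gene symbols, with a value whose unit is called signal here. Signal is the mean over the 40-bp bins of an exon of the reads in a bin, multiplied by 1 factor per library. This was checked on the values: with a tolerance of 0.05 read, 100% of the 21509 to 22193 exons checked per library held a whole number of reads. A single read in a bin was worth 0.340 and 0.390 signal in the control libraries and 0.372 and 0.476 in the knockdown libraries. Relative depth was therefore 1.40 and 1.22 in the control libraries and 1.28 and 1 in the knockdown libraries. What total the factor scales to is not stated, so absolute depth is unknown. The deposited peak lists give the start and end of each peak and no other unit, so no height, score or p-value could be used. Intervals on shares of peaks are 95% Wilson intervals and cover counting error only.

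Overlapping exons of a gene were grouped into 68582 clusters, the longest exon stood for its cluster, and the gene value was the mean over clusters weighted by bins. This differs from a plain sum because the files hold coverage and not counts. Exon positions are printed as the files give them and can be off by 1 bp. Peak starts are counted from 1. Symbols were matched to a current name table for names only. The table held 12228 as current symbols and 4031 as synonyms, and it left 250 unmatched, 78 of them among the genes tested. Reads in exons that overlap another gene counted for both, and 993 genes had over 50% of their exonic length in such exons.

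Knockdown and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(signal + 1), two-sided, in the 6050 genes with a mean signal of 1 or more. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Log2 changes are differences of these logs, so they are smaller than the ratio of the signals for genes of low signal. Gene lists were tested against all other tested genes with camera at its preset correlation of 0.01, and again with an estimated correlation. The second run has only the residual degrees of freedom, 2 in the main fit and fewer with a library left out. It therefore rarely passes, and a call lost in it decides little. The 18 lists were fixed before the data were examined. They were dTet, yellow, RNA modification genes, cytoplasmic ribosomal proteins, translation factors, RNA interference, antimicrobial and immune genes, heat shock and the ecdysone response. The others were cell cycle and replication, glycolysis, oxidative phosphorylation, the proteasome, developmental signalling and hemocyte markers. Markers of neurons and glia, of muscle and of the germline and ovary completed the set. Lists with fewer than 5 tested genes were not tested. The comparisons and the rule for named genes were fixed at the same time. The rule takes dTet and the 10 genes with the largest change in each direction among those past the threshold. Where none pass, it takes the 10 smallest p in each direction, as values. It also takes the 4 members of each list with the smallest p, the 5 widest peaks in each of the classes yellow list alone, both lists (by yellow-list width) and dTet list alone, and the 5 genes with the most yellow peaks in their exons.

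Peaks were intersected with bedtools 2.31.1, and 1 shared bp counted as overlap. A peak on an assembled arm (X, 2L, 2R, 3L, 3R or 4) was exonic if it touched an exon and intronic if it lay within the span of a gene without touching one. A gene had a peak if the peak touched one of its exons. Genes were counted as detected at a mean control signal of 1 or more, which gave 6086. Overlap of gene lists was tested with Fisher's exact test, and expression of genes with a peak with a permutation test of the difference in medians (100000 permutations). The knockdown change of such genes was tested with camera and with 10000 random lists of genes of like mean signal. Other intervals are bootstrap intervals, except those of odds ratios, which are exact. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

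The procedure was tested on simulated data of 6050 genes. It called 1 of 50 genes changed 1.5-fold, 34 of 50 changed 2-fold and 46 of 50 changed 4-fold, and 4 of 5850 unchanged genes. Folds were applied to signal + 1, with noise independent between genes and 50 genes changed 8-fold in the same run. A 2-fold change in a low signal is smaller on that scale, and large folds eased the threshold for small ones. These rates can therefore overstate the power for real genes. In a separate run with no gene changed, 2 of 6050 genes were called. With the same independent noise, a list shifted by 0.3 was called and 0 of 13 other lists were. The rate for lists of correlated genes was not tested. The peak overlap recovered 239 of 239 moved peaks, and the permutation test called 4 of 100 random gene sets.

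Alternatives planned from the start were quantile normalization, limma without a trend, no filter, a filter of 5 in at least 2 libraries, a pseudocount of 0.1, the replicate number as a replicate block, leaving out each library, other thresholds, an estimated correlation, other overlap rules, the widest 50% of each peak list, and other backgrounds. Chosen after the data were seen were exons tested one by one, genes of 10 or more bins with no exon shared, matching on exonic length, the split into arms and unplaced scaffolds, the share of each list with a peak, the share of genes on chromosome X, and mitochondrial ribosomal proteins as a further list. Count-based tools (edgeR, DESeq2) were planned only for counts and were not applied to coverage. Expression per kb was left out because signal is already a mean per bin. Testing transcripts in place of genes had no meaning because the files hold exons. Base composition and untranslated regions were left out because no dm3 genome or transcript annotation was at hand.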

Results

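Transcript levels were measured by polyA RNA-seq in S2 cells, a hemocyte-like Drosophila line, in 2 control and 2 dTet knockdown libraries. dTet encodes the fly Tet dioxygenase, an enzyme family known to oxidise methylcytosine to hydroxymethylcytosine. Sites of the modified base in RNA were mapped by hMeRIP-seq, which sequences RNA pulled down with an antibody to hydroxymethylcytosine, in 1 sample of yellow CRISPR cells and 1 of dTet CRISPR cells. Between 9156 and 9708 genes had a signal above 0 per RNA-seq library. A single read in a bin was worth 0.340 signal in the deepest library, control 1, and 0.476 in the shallowest, knockdown 2. Control 1 also stood apart in evenness along genes. In 1509 genes of 3 or more exons, the median log2 ratio of signal between the outer parts of a gene was 1.36 in control 1, against 0.83 in control 2, 0.87 in knockdown 1 and 0.77 in knockdown 2. Ribosomal protein genes took 6.20% and 5.26% of the signal in the controls and 5.68% and 5.97% in the knockdown libraries.

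The first comparison asked whether dTet RNA was lower in the libraries named as its knockdown. dTet is listed as CG43444, with a span of 2786206 to 2879157 on 3L (dm3) and 351 bins of exon. Its signal was 7.47 ± 0.76 (SD, n = 2) in the controls and 5.74 ± 1.22 (SD, n = 2) in the knockdown libraries. The single values were 6.93 and 8.01 against 4.88 and 6.60, so each knockdown library lay below each control library. The log2 change was -0.34 with a standard error of 0.21, and it did not pass the test (limma, unadjusted p = 0.144, adjusted p = 0.9995). The first exon in genome order, from 2786206 to 2791276, carried most of the signal, at 14.8 in the controls and 11.1 in the knockdown libraries. Exon 5 stood at 6.03 and 3.95, while exon 6 stood at 6.13 and 6.21 and exon 7 at 6.08 and 6.88. None of the 8 dTet exons tested passed (limma, adjusted p = 0.999). The labels do not name the knockdown reagent. Had a double-stranded RNA made of dTet sequence been used, any of its reads in these polyA libraries would count in the exons. Whether there were such reads cannot be seen here. The change moved by over 1.5 times with single libraries, from -0.15 without knockdown 1 to -0.52 without knockdown 2.

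**Figure D1:**
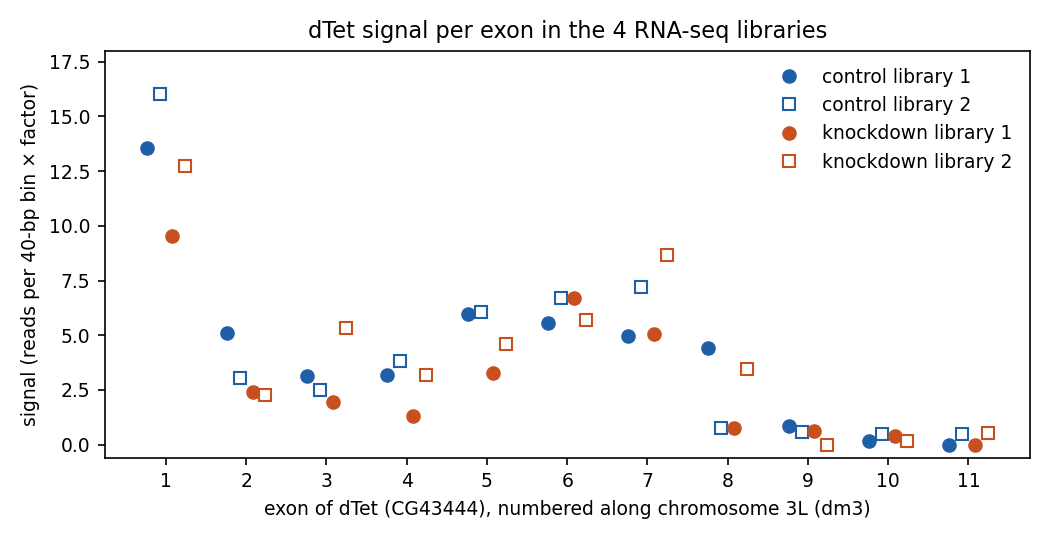
Signal of each dTet exon (mean reads per 40-bp bin times the library factor), numbered along chromosome 3L, with 1 point per RNA-seq library and no error bars. In exon 1 both knockdown libraries, at 9.54 and 12.8, lie below both controls, at 13.5 and 16.0, while in exon 6 the groups overlap.

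The next comparison asked which transcripts differ between the libraries labelled dTet knockdown and the controls. Of 6050 genes tested, 0 passed at an adjusted p of 0.05 with limma, with or without a trend, and 245 had an unadjusted p under 0.05, where chance alone gives 302.5. The smallest adjusted p was 0.206 with a trend and 0.0870 without one. The genes given next are the extremes of that ranking, as values, and each lay on the same side in 4 of 4 pairs of knockdown and control libraries. TotM, a secreted stress peptide of the Turandot family (2L, 5329856 to 5330463), had 10.1 ± 1.36 signal in the controls and 25.8 ± 4.82 in the knockdown libraries (SD, n = 2 each). Its log2 change was 1.26 with a standard error of 0.20 (limma, adjusted p = 0.304). CG1648 stood at 4.19 and 8.92 signal, a log2 change of 0.93, and CG10960 (now nebu) at 1.58 and 4.30, a log2 change of 1.04. On the lower side stood CG15168, a subunit of the endoplasmic reticulum membrane complex (now EMC5), with 4.65 ± 0.94 and 1.13 ± 0.13 signal (SD, n = 2 each; limma, adjusted p = 0.304). Gbp, listed with 9.05 and 4.56 signal, had -0.86. The infection-induced peptide gene edin had 4.88 and 1.88 signal and -1.01. The endosomal GTPase gene Rab4 had 7.76 and 3.99 signal and -0.81. CG30273 and CG1662 had log2 changes of -0.97 and -0.99.

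The other 11 of the 20 genes were mostly loci annotated as short noncoding RNAs, of a few bins. On the higher side these were mir-995 (log2 change 1.67), mir-1007 (1.26), mir-998 (1.23), CR44124 (1.21), snoRNA:Psi28S-3405d (1.12), snoRNA:Psi18S-1820 (0.99) and a small noncoding RNA gene inside Msp300 (0.82). On the lower side were snoRNA:Psi18S-841d (-1.74), CR44898 (-1.44), snmRNA:184 (-1.20) and mir-4941. The last is listed at 0 in both knockdown libraries and at 2.72 and 2.86 in the controls, and all of its length lies in an exon of Notum. CR44898 shared 99.8% of its length with CR44897 and lea, and CR44124 shared 43.9% with l(1)G0222. The gene inside Msp300 and snmRNA:184, which lies in dom, shared 100% of their length with those genes. snoRNA:Psi28S-3405d lies within the span of Hrb98DE, and mir-995 stood near the floor in the controls, at 0.113 and 0.521 signal. With polyA libraries, reads at these loci cannot be told from reads of longer transcripts across them. Without control 1 CR44124 had a log2 change of 0.76. Log2 changes from low signals depended on the pseudocount: at 0.1 they were 3.15 for mir-995, 2.33 for mir-998, 2.35 for CR44124, -3.596 for snoRNA:Psi18S-841d and -1.52 for CG1662, and none passed. Without knockdown 1, 3 genes passed: mir-2493, snoRNA:Me28S-G3113a and snoRNA:Psi18S-841d, of which 1 rose and 2 fell. Tests of 23023 exons one by one and of 3323 genes with 10 or more bins and no shared exon, both chosen after the data were seen, gave 0 past the threshold. Their counts at an unadjusted p under 0.05 were 911 and 127. On simulated data of this size, 34 of 50 genes changed 2-fold were called and 1 of 50 changed 1.5-fold. Those folds applied to signal + 1 and were simulated beside larger ones. The shares can therefore overstate the power for real genes, above all those of low signal.

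**Figure D2:**
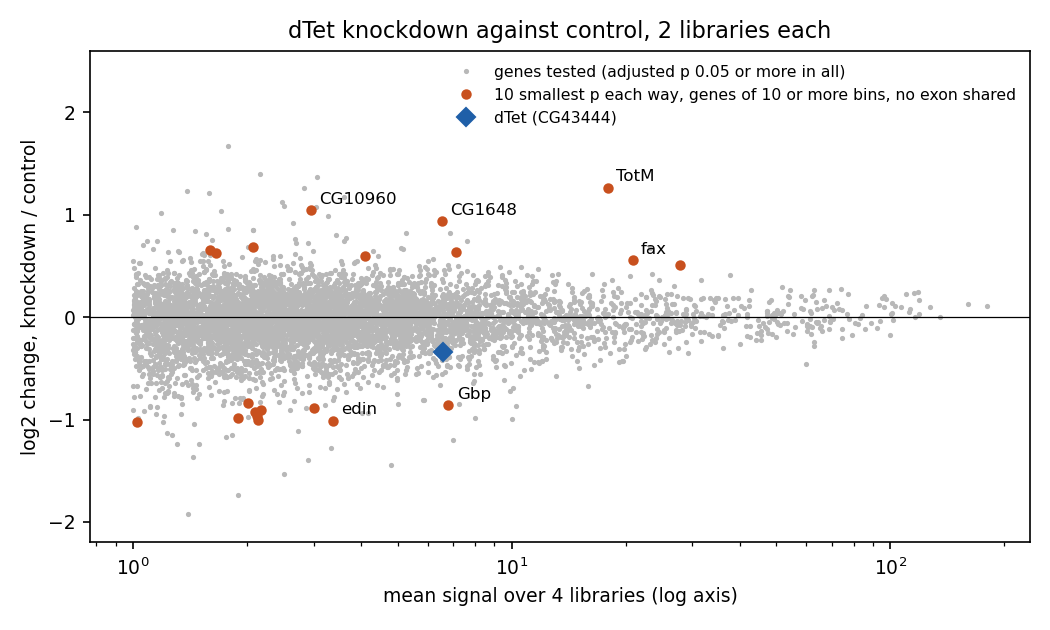
Log2 change (knockdown over control, 2 libraries each) against mean signal over the 4 libraries on a log axis, with 1 point per tested gene. Orange points are the 10 smallest p in each direction among genes of 10 or more bins with no shared exon, a choice made after the data were seen. TotM lies highest of these at 1.26, and dTet (blue) lies at -0.34.

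Gene groups were compared next, and in these 14 tested lists no list and no member passed over all genes. RNA interference genes had a median log2 change of 0.10, with 10 tested, 7 higher and 3 lower. Their p was the smallest of the lists (camera, adjusted p = 0.619). Their median was 0.05 without control 1 and 0.24 without control 2. AGO2, the slicer of the small interfering RNA pathway, stood at 8.58 and 13.4 signal in the controls and 13.5 and 15.8 in the knockdown libraries, and the RNA helicase gene Rm62 at 23.5 and 31.9 against 34.0 and 37.1. Among 21 antimicrobial and immune genes (median 0.02, adjusted p = 0.857), 11 were higher and 10 lower. The sign of this median was not stable: it was 0.07 without control 1 and -0.27 without knockdown 2. Among members of 10 or more bins with no shared exon it was -0.17. In this list 1 gene, TotM, passed when adjusted over the list alone (limma, adjusted p = 0.00403), and it rose. The antibacterial peptide gene DptB had log2 change 0.91, and the recognition gene PGRP-SD and the antibacterial peptide gene Dro had -0.56 and -0.50. In the other 13 tested lists 0 members passed when adjusted over the list alone.

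Hemocyte markers, which S2 cells express, had a median log2 change of -0.14 (16 tested, 5 higher and 11 lower, adjusted p = 0.631). The basement membrane peroxidase gene Pxn stood at 2.44 and 1.10 signal (log2 change -0.72) and He at 5.51 and 8.11 (0.51). The 32 proteasome genes had a median of -0.09 (12 higher, 20 lower, adjusted p = 0.631), with Prosalpha2 at -0.55, Prosbeta7 at -0.48 and Rpn11 at -0.47. Cell cycle and replication genes (36 tested, 19 higher and 17 lower, adjusted p = 0.966) had a median of 0.01 and a mean of -0.03. They included the securin gene pim at -0.60, the cyclin-dependent kinase inhibitor gene dap at -0.51 and the replication helicase gene Mcm5 at 0.58. Glycolysis genes (12 tested, 9 higher and 3 lower, median 0.07, adjusted p = 0.631) included Ald at 0.45 and Pglym78 at -0.52. Oxidative phosphorylation genes (25 tested, 9 higher and 16 lower, median -0.08, adjusted p = 0.857) included CoVIIc at 0.41 and Pdsw at -0.35.

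Cytoplasmic ribosomal protein genes showed a median log2 change of 0.02 (82 tested, 43 higher and 39 lower, adjusted p = 0.631), with RpL13 at 0.22 and RpS15Ab at -0.37. Translation factors had a median of -0.07 (35 tested, 13 higher and 22 lower, adjusted p = 0.857), with Trip1 at -0.36 and eIF4G at 0.32. RNA modification genes had -0.02 (16 tested, 7 higher and 9 lower, adjusted p = 0.857, test direction up). Among them the cytosine methyltransferase gene Nsun2 stood at -0.17 and the adenosine deaminase gene Adar at 0.23. Ecdysone response genes had 0.02 (13 tested, 8 higher and 5 lower, adjusted p = 0.857), with ImpL2 at -0.12 and Kr-h1 at 0.12. Developmental signalling genes divided evenly (30 tested, 15 higher and 15 lower, adjusted p = 0.631), with Stat92E at 0.31 and hpo at -0.31. Heat shock genes had a median of -0.14 (13 tested, 5 higher and 8 lower, adjusted p = 0.972). Hsp23 stood at 14.8 ± 11.7 signal in the controls and 8.90 ± 1.74 in the knockdown libraries (SD, n = 2 each), so its control libraries differed by more than the groups.

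Lists of markers of other cell types had low medians. Of 20 neuron and glia markers 4 were tested (Syx1A, elav, mbl and moody; the list's median control signal was 0.052), and of 19 muscle markers 2 were tested (Tm1 and Msp300; 0.025). Germline and ovary markers had 7 of 20 tested, with a median log2 change of 0.04 (4 higher and 3 lower, adjusted p = 0.631). The yellow gene had 0.503 and 1.08 signal in the controls and 1.88 and 1.12 in the knockdown libraries (log2 change 0.48, limma adjusted p = 0.9995). With an estimated correlation 0 lists passed (camera, smallest adjusted p = 0.991), but that run has 2 residual degrees of freedom and rarely passes. Without control 1, the library with the least even coverage, 5 lists passed: ribosomal protein, heat shock, glycolysis and oxidative phosphorylation genes upward and hemocyte markers downward. Without control 2, 5 lists also passed: RNA interference genes upward, and ribosomal protein, heat shock, oxidative phosphorylation and proteasome genes downward, so that 3 of these lists turned direction with the control library left out. Without knockdown 1, heat shock genes had a median log2 change of -0.63. None of the calls with a library left out held with an estimated correlation. Fewer degrees of freedom then remain, so that loss decides nothing about them.

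The hMeRIP comparison asked where RNA hydroxymethylcytosine was called in cells edited at yellow and in cells edited at dTet. The data used here do not show what the edit did to the dTet gene. With 1 sample per line, the lists describe these samples and no test of the genotype was possible. The yellow list held 1018 peaks over 753 kb and the dTet list 964 peaks over 908 kb. Of the yellow peaks, 529 (52.0%, 95% interval 48.9 to 55.0) met a dTet peak by 1 bp or more, and 519 of the dTet peaks (53.8%, 50.7 to 57.0) met a yellow one. On the assembled arms the yellow list had 479 peaks with a median width of 544 bp, of which 71.6% (67.4 to 75.5) were shared. The dTet list had 591 there, with a median width of 987 bp, of which 56.2% (52.1 to 60.1) were shared. On unplaced scaffolds, which hold repeats, the order was the other way: 535 yellow peaks (34.6% shared, 30.7 to 38.7) and 371 dTet peaks (50.1% shared, 45.1 to 55.2). This split was made after the data were seen.

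**Figure D3:**
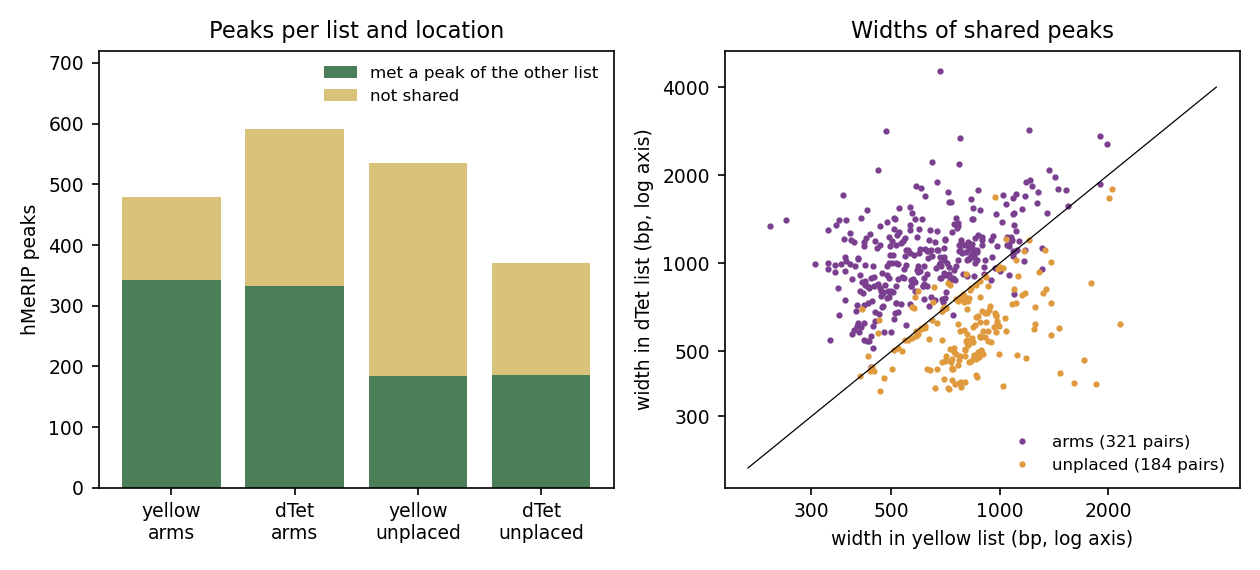
Left, number of hMeRIP peaks per list on the assembled arms and on unplaced scaffolds, divided by whether a peak met one of the other list. Right, widths in bp (log axes) of peaks that met exactly 1 peak of the other list, with the line of equal width. On the arms 307 of 321 pairs were wider in the dTet list, and on unplaced scaffolds 17 of 184 were.

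Ranked by width in the yellow list, the widest peaks found in both lists lay in the genes of the collagen IV chains, the main collagens of basement membrane. They were in Cg25C (now Col4a1) at 5030979 to 5033832 (2854 bp) and 5033934 to 5036113 (2180 bp) on 2L, and in vkg at 5015615 to 5018449 (2835 bp) on 2L. Both genes had high control signals, at 77.6 and 68.2. The remaining members of that class lay on unplaced scaffold sequence (Uextra), without an exon, at 5579505 to 5581668 and 28093532 to 28095587. The widest peaks of the dTet list alone lay in CG7358 (now Flacc, a subunit of the RNA adenosine methyltransferase complex; X, 18785048 to 18787772), larp (3R, 24147966 to 24150587), Ect4 (now Sarm; 3L, 8098115 to 8100378) and Xrp1 (3R, 14750706 to 14752625). A further one touched an exon of the ribosomal RNA pseudogene CR41602 on Uextra (15781959 to 15784112), with 27.7% of its length in exons. The 5 widest of the yellow list alone were all on Uextra without an exon, the widest at 27958238 to 27960518 (2281 bp). On the arms, a choice made after the data were seen, the widest yellow-list peaks without a dTet counterpart were in CG2839, dTet itself, CG32767, l(1)G0289 and Act5C. The peak in CG2839 (2L, 626430 to 628270) lay in a gene with a control signal of 0.

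The dTet gene carried 4 peaks in each list. A pair of yellow peaks lay in its first exon in genome order, at 2788425 to 2789523 and 2789761 to 2791369. The second of them ran past the end of that exon, with 1516 of its 1609 bp inside. The dTet list had a peak over the first, at 2788510 to 2789292, and none over the second. Intronic peaks at 2824175 to 2825266 and 2828377 to 2829326 in the yellow list each met a dTet-list peak. The dTet list had a further intronic peak at 2829626 to 2830170. The yellow gene had 0 peaks in either list.

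**Figure D4:**
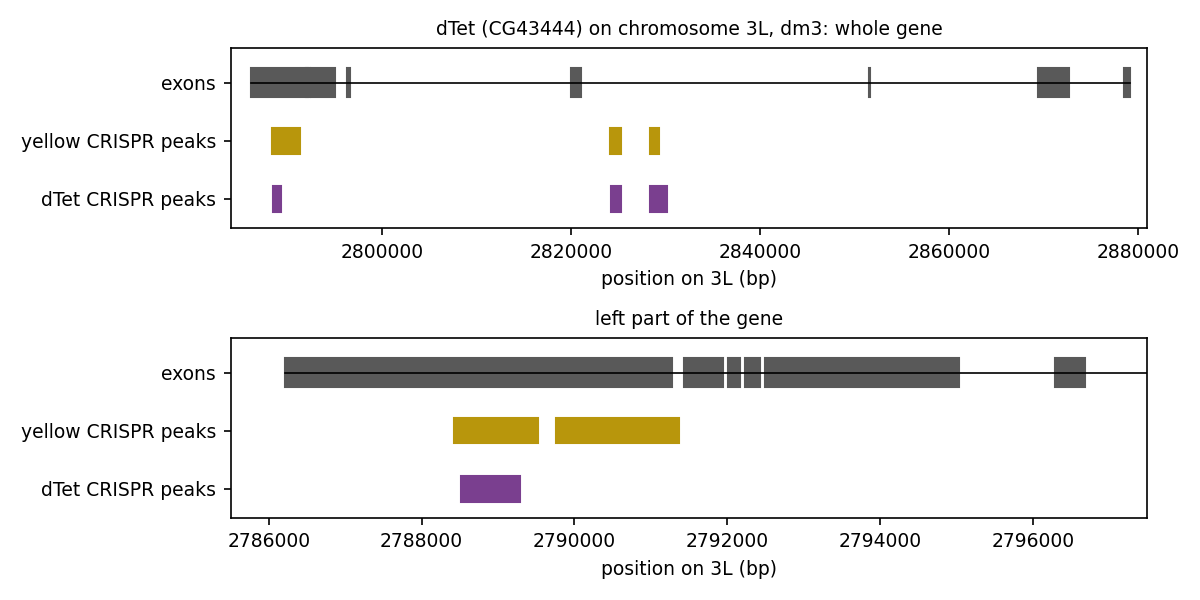
Map of dTet on chromosome 3L (dm3, position in bp) with its exons and the peaks of both hMeRIP lists, for the whole gene and enlarged for its left part. The yellow-list peak at 2789761 to 2791369 has no counterpart in the dTet list.

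The genes under the peaks were compared between both lists among the 6086 genes detected in the control RNA-seq libraries. A yellow peak touched an exon of 340 of them and a dTet-list peak an exon of 471; peaks within introns were not counted here or in the comparisons that follow for genes. Both lists named 283 genes, where independent lists would share 26.3. The odds ratio was 147 (95% interval 106 to 205, Fisher's exact test, two-sided, p = 2.4e-295). Random dTet-size lists of like signal and exonic length, added after the data were seen, shared at most 108 genes with the yellow list. Genes with the most exonic yellow peaks were fs(1)h, a bromodomain protein gene, with 3 in each list, mask with 3 in each list, rudhira with 3 and 2, and nej, the fly CBP acetyltransferase gene, with 3 and 4. In all, 45 genes had 2 or more exonic yellow peaks, among them Cg25C, with 2 and 1.

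Genes with a yellow peak were more highly expressed than those without. Their median control signal was 5.58 (n = 340), against 2.91 in 5746 detected genes without one. The log2 difference of the medians of signal + 1 was 0.75 (95% interval 0.60 to 0.96, permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give). The collagen genes Cg25C and vkg and Act5C (91.6 signal) stood at the upper end, and 27 genes with a yellow peak had a control signal below 1. Peak genes were also longer, with a median exonic length of 4.76 kb against 2 kb. The difference was 1.48 when the longest 50% of genes were left out, which kept 41 genes with a peak. Genes are not independent replicates, so this p describes the lists.

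The last expression comparison asked whether transcripts that carry a yellow peak differ between the libraries labelled dTet knockdown and the controls. The 340 yellow-peak genes had a median log2 change of 0.01, with 177 higher and 163 lower and 0 past the threshold, over all genes or adjusted over the list alone. Camera gave p = 0.0353, and 0.0705 after adjustment over the 2 sets tested (0.0995 with an estimated correlation). Their median lay at percentile 99.5 of random lists of like signal, whose 95% range was -0.04 to 0.01. It lay at percentile 45.0 once the random lists were matched on exonic length as well, a match added after the data were seen. The 57 genes with a peak in the yellow list alone had a median of 0.00, with 29 higher and 28 lower. Camera gave an adjusted p of 0.482 for them, and their median lay at percentile 76.0 (37.3 with exonic length matched too). Without control 2 the yellow-peak set passed at the preset correlation (median 0.02, adjusted p = 0.0452). It also passed among genes of 10 or more bins with no shared exon (median 0.02, adjusted p = 0.0353), a setting added after the data were seen. Neither setting passed with an estimated correlation, but that run has too few degrees of freedom to decide. Among genes of 10 or more bins with no shared exon it gave unadjusted p = 0.0529 (camera). The median of the yellow-only genes was negative without control 1, without control 2 or without knockdown 2. It was also negative with no filter (-0.0011) and with the filter of 5 (-0.0102), where the yellow-peak median was 0.0072.

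By location, 80.2% of yellow peaks on the arms (384 of 479, 95% interval 76.4 to 83.5) touched an exon, and 91.7% of dTet-list peaks (542 of 591, 89.2 to 93.7) did. The other 95 and 49 lay in introns. In neither list did a peak on the arms lie outside a gene span, although the spans cover 72.2% of arm length. Whether the lists had been filtered on genes is not stated, so the exonic shares hold for the lists as deposited. Counts on X, 2L, 2R, 3L and 3R were 153, 86, 56, 82 and 101 in the yellow list and 157, 103, 73, 113 and 145 in the dTet list. Chromosome X was overrepresented among peak genes, a comparison made after the data were seen. It held 17.2% of detected genes, but 30.6% of yellow-peak genes (104 of 340, odds ratio 2.25, Fisher's exact test, p = 3.0e-10) and 25.7% of dTet-list genes (121 of 471, odds ratio 1.76, p = 1.1e-06). Random lists of like signal and exonic length had at most 96 and 119 such genes among 10000 draws each. fs(1)h, nej and rudhira are X-linked.

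**Figure D5:**
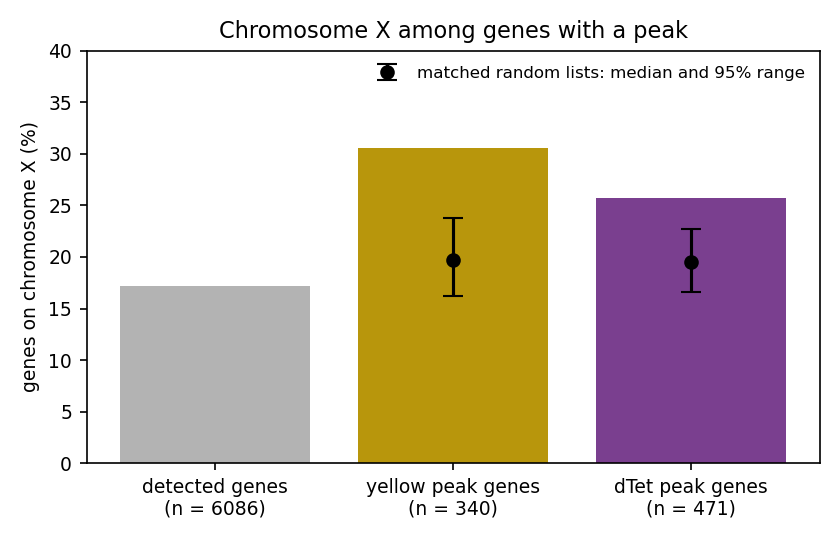
Percent of genes on chromosome X among detected genes and among detected genes with a peak in each list (bars), with the median and 95% range of 10000 random lists of like signal and exonic length (points and lines). The yellow-peak genes stand at 30.6% against a matched median of 19.7%, and the dTet-list genes at 25.7% against 19.5%.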

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

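Settings that restrict genes to 10 or more bins with no shared exon, test exons one by one, match on exonic length, split arms from unplaced scaffolds or use the dTet list for expression were chosen after the data were seen. Over 268 alternatives of 33 results, 251 kept their direction and their side of the threshold or stayed within the spread. For the knockdown change of genes with a peak, this count left out 4 settings. These were limma without a trend, no filter, the filter of 5 and the pseudocount of 0.1. The median of yellow-only genes turned negative with no filter (-0.0011) and with the filter of 5 (-0.0102). Of 191 alternatives for the 20 named genes 190 did so, and the exception was snoRNA:Psi18S-841d without knockdown 1 (log2 change -2.14). These genes were picked for small p in the same libraries, and those below a filter were not counted under it. The count of 190 is therefore little test of them. Leaving out each library in turn gave 0 to 3 genes past the threshold, 0 to 5 gene lists, and a dTet log2 change of -0.52 to -0.15, which never passed. A lone library was then assumed to vary like the other group. With the replicate number as a replicate block, 0 genes (245 at unadjusted p under 0.05) and 0 lists passed and the dTet change was -0.34. The median change of yellow-peak genes ranged from 0.0138 to 0.0207 over left-out libraries and passed without control 2 at the preset correlation. It was 0.0236 in genes of 10 or more bins with no shared exon, where it passed, and -0.0010 for the widest 50% of the list, where it turned negative, with adjusted p from 0.0353 to 0.766 over these settings. With an estimated correlation neither setting passed, but that run has too few degrees of freedom to decide (camera, unadjusted p = 0.0529 in the genes with no shared exon). Under quantile normalization it was 0.0327 for yellow-peak and 0.0264 for yellow-only genes, which did not pass. Over left-out libraries yellow-only genes ranged from -0.0345 to 0.0220, being -0.0157 without control 1, -0.0246 without control 2 and -0.0345 without knockdown 2. The percentile of yellow-peak genes dropped to 45.0 with random lists matched on exonic length. The share of yellow peaks that met a dTet peak was 39.6% at a reciprocal overlap of 50% and 27.7% for the widest 50% of each list. In the latter it rose from 71.6% to 86.2% on the arms and dropped from 34.6% to 4.40% on unplaced scaffolds, which held 364 of the 509 yellow peaks kept. The share of dTet-list peaks that met a yellow one dropped there to 32.8% and 13.8%, from 56.2% and 50.1%. The cause of the moves with single libraries was not tested. With 2 libraries per group, 1 of 50 simulated genes changed 1.5-fold in signal + 1 was called. The effect of depth was not tested.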

Other observations

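In this part, the gene lists with peaks, the mitochondrial ribosomal list, the named unshared genes, the match on exonic length, the reading of the yellow-only percentile, the comparisons of peak widths between lists and of arms with unplaced scaffolds, and the comparisons of shared peaks on chromosome X were chosen after the result was seen. The draws matched on peak width and on gene signal were set out before their results were seen. Heat shock genes stood out among genes with a peak in the dTet list: 7 of 14 detected members had one (Hsc70-3, Hsc70-4, Hsp22, Hsp27, Hsp60, Hsp68 and Hsp83; odds ratio 12.1, Fisher's exact test, adjusted p = 0.000473). Random genes of like signal and exonic length had a median of 2 (95% range 0 to 5). That signal came from the control RNA-seq libraries, and expression in the dTet CRISPR cells was not examined. Heat shock genes varied between the control libraries: their median knockdown change was 0.37 without control 1 and -0.74 without control 2. The match therefore does not cover their RNA level in the dTet CRISPR sample. RNA modification genes had 4 of 15 (Fib, Nop56, Nop60B and YT521-B; matched range 0 to 3), with an adjusted p of 0.0815 against all detected genes. In the yellow list 4 of 14 heat shock genes had a peak (Fisher's exact test, adjusted p = 0.0714), within the matched range of 0 to 4. The difference between the lists was not tested. RNA interference genes (4 of 10: AGO2, Fmr1, Rm62 and vig; adjusted p = 0.0270) and hemocyte markers (5 of 16: Cg25C, Ppn, srp, vkg and zfh1; adjusted p = 0.0270) were also above all detected genes in the dTet list, but within the range of matched genes (1 to 5 and 2 to 8). Oxidative phosphorylation genes (0 of 25) and immune genes (0 of 22) had no peak in either list, and ribosomal protein genes had 1 of 82 in the yellow list and 5 of 82 in the dTet list. These counts lay within the ranges of matched genes. Some genes had several exonic dTet-list peaks and 0 exonic yellow ones: msn, a kinase gene of the JNK pathway, had 6, and the RNA-binding protein gene Syp had 3.

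Among genes of 10 or more bins with no shared exon, further extremes of the knockdown comparison included mitochondrial genes. The mitochondrial ribosomal protein genes mRpL49 and mRpS26 stood at 3.07 and 3.18 signal in the controls and 1.13 and 1.10 in the knockdown libraries. mTerf3, a mitochondrial transcription termination family gene, stood at 1.72 and 0.328. Over all 64 tested mitochondrial ribosomal protein genes 39 were lower and 25 higher, with a median of -0.13 (camera p = 0.0925, and 0.446 with an estimated correlation). Without control 1 the median was 0.00 (p = 0.998), and without control 2 it was -0.25 (p = 0.0202, and 0.298 with an estimated correlation). Without knockdown 1 it was -0.02. In the 5 genes left by the filter of 5 signal it was 0.02. Among the 27 of 10 or more bins with no shared exon the median was -0.16 (p = 0.0146, and 0.211 with an estimated correlation). The median of all 64 lay at percentile 0.95 of random lists of like signal and at percentile 49.4 once exonic length was matched too. On the higher side were fax (log2 change 0.56) and the lipoprotein receptor gene LpR2 (0.64). None of these passed the test over all genes (limma, smallest adjusted p = 0.903).

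Yellow-peak genes had a slightly higher median knockdown change than random genes of like signal, at percentile 99.5. Exonic length is a candidate explanation, since the median lay at percentile 45.0 once length was matched too. If loss of a mark that needs dTet raised transcript levels, genes with a peak in the yellow list alone would lie above the range of random lists. They lay at percentile 76.0 of random lists of like signal, whose 95% range was -0.085 to 0.041. With exonic length matched too, they lay at percentile 37.3. A mark could need dTet without changing transcript levels, and the lower dTet signal in the knockdown libraries did not pass its test. These percentiles therefore do not decide whether the mark needs dTet. Genes with a peak in the dTet list alone lay at percentile 99.8 of random lists of like signal, and at 92.4 with length matched too. For the 57 genes with a peak in the yellow list alone, an effect of the mark and chance cannot be told apart. The knockdown of dTet was not established by its test, and each peak list rests on 1 sample per line.

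Peaks shared by both lists were wider in the dTet list on the arms, by a median of 363 bp (95% interval 331 to 395, 321 pairs). On unplaced scaffolds they were narrower, with a median difference of -245.5 bp (-285 to -223, 184 pairs). The widths thus did not shift in the same direction everywhere. This sign was seen before a deeper or more enriched dTet CRISPR library as a whole was considered. It is therefore no test of that explanation. Peaks found in 1 list alone were also more often on the arms in the dTet list (odds ratio 3.598, 2.72 to 4.78), but these counts led to the idea of a different split of reads between arm transcripts and unplaced repeats and are no test of it. Such a split, from the RNA preparation or from the edited gene, and other differences between the samples cannot be told apart with 1 sample per line.

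Exonic yellow peaks on chromosome X lacked a dTet counterpart in 43 of 123 cases (35.0%), against 41 of 261 (15.7%) on the other arms (odds ratio 2.88, 1.70 to 4.89, Fisher's exact test, p = 3.6e-05). Intronic yellow peaks lacked one in 18 of 30 cases on X and 34 of 65 on other arms (odds ratio 1.36, 0.523 to 3.65, Fisher's exact test, p = 0.514). Narrower peaks on X or lower signal of the genes under them could give the exonic difference, but at most 40 unshared peaks occurred in 10000 draws of exonic yellow peaks matched on width, and at most 42 in draws matched on control signal. Each draw matched 1 of these alone, although X peaks were both narrower (median 547 against 579 bp) and in genes of lower signal (3.92 against 6.32). Peaks of 1 gene were also drawn as separate units. Width and signal together were not matched and stay open. Less RNA from X in the dTet CRISPR cells would lower the share of X among dTet-only peaks. The odds ratio was 0.964 for exonic peaks (0.647 to 1.43, Fisher's exact test, p = 0.923), and 0 of 9 intronic peaks on X against 10 of 40 on other arms were dTet-only (odds ratio 0, up to 1.88), so this and an unchanged amount cannot be told apart. A difference between the cell lines, including the edited gene, is also open and was not tested.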
